A study of Mus musculus with 6 samples.

How the data were processed

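Haematopoietic stem and progenitor cells from the bone marrow of Taf1 KO and WT mice were profiled with the 10x Genomics Chromium single-cell system, in 3 libraries per genotype, per the labels. Per the submitters' processing notes, Cell Ranger 4, Seurat, DESeq2 and Scanpy 1.9.1 were used and the genome build was mm10; the notes list tools without their order or role. The values used here are whole-number UMI counts per gene and cell barcode that the authors deposited as filtered matrices, with no normalization. Matrices were analysed for WT replicates 1 and 3. Of the other 4 libraries only the deposited barcode and gene lists were used, which hold names and no measurements, and their expression was not analysed here. Groups came from the genotype label; replicate numbers follow sample order, since the labels give none, and pair no samples across genotypes. The comparisons, tests, gene lists, cell type markers, rule for named genes and most alternatives were fixed before the data were examined; approximate barcode numbers had been visible from file sizes by then.

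Barcode numbers were compared between genotypes with an exact two-sided permutation test of the group means over all 20 assignments (scipy 1.17.1). For each pair of libraries the number of shared barcodes was set beside the number expected from independent draws, with the size of the barcode list estimated from the other pairs; an exact Poisson test of each pair and a chi-square test of 1 rate for all pairs were added after the numbers were seen. In the matrices, a cell was kept with at least 500 genes, at least 1000 UMIs and under 10% mitochondrial UMIs. Scrublet, run per library in scanpy 1.11.5 with its automatic threshold, marked 149 of 6089 cells in WT replicate 1 and 265 of 8091 in WT replicate 3 as doublets, which were removed. This left 5940 cells with 170852120 UMIs and 7826 cells with 212813483 UMIs.

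Counts were scaled to 10000 UMIs per cell and log-transformed for clustering. The 2000 most variable genes were chosen with library as batch after removing every gene of the lists below, Xist, Y-linked and mitochondrial genes, and z-scored within each library. Leiden clustering (leidenalg 0.10.2, resolution 1) ran on 15 exact nearest neighbours in 30 principal components and gave 25 clusters. A cluster took the name of the class with most markers among its 10 leading genes, from 15 marker sets, with at least 3 raised markers, and the suffix -like says that names rest on markers. Clusters without a class marker among their leading genes stayed unnamed, a rule set after the clusters were seen. Genes that correlate with the held-out lists, such as other cell cycle genes, remained among the clustering genes, so the lists are not fully independent of the classes. Shares have exact Clopper-Pearson intervals at the 95% level.

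For expression, counts were summed per class and library for the 7 named classes with at least 100 cells in each library, giving 14 sums. These were fitted in edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr and library as a block, since classes of 1 library come from the same cell preparation, and tested with the quasi-likelihood test with 6 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg over the 12776 genes in the fit, with a threshold of 0.05. With 2 libraries, the spread is pooled over classes, which share an animal or preparation, so p-values describe these libraries more than mice at large. The SE given with an edgeR log2 fold change is its absolute value divided by the square root of the test's F statistic, not a separate estimate. CPM per class use edgeR's scaled library sizes and log2 values for set tests a prior count of 2. Only genes of 21 lists are reported, since other genes took part in clustering: TFIID, SAGA, Mediator, RNA polymerase II, other general transcription factors, pausing and elongation, ribosomal proteins, oxidative phosphorylation, glycolysis, heme synthesis and iron, cholesterol synthesis, antioxidant, lysosome, interferon response, immediate early and stress, p53 targets, apoptosis, S phase, G2 and M phase, cytokine receptors and surface signalling, and epigenetic and cohesin genes of myeloid malignancy. Of 710 list genes, 705 were found by symbol and 693 passed the filter. Lists were tested as sets with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated correlation, adjusted over 84 tests.

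Genes were named by a fixed rule: Taf1 and Tbp always, every TFIID gene that passed, and from each list the largest rise and largest fall among genes with an adjusted p under 0.05, the same sign in both libraries and at least 10 CPM in 1 of the compared classes; some of these are not named in the text. The WT libraries were set side by side by the 10 largest CPM ratios, with counts under 3 set to 3 for the ratio. Interferon medians were also set against the all-gene median of the same fit, and taken from UMIs per cell per library (0.5 added to each sum, no scaling); both were added after the result was seen. Coordinates are from GENCODE mouse release M21 (GRCm38, the build the notes name), in which 32158 of the 32285 gene identifiers were found. The edgeR step was tested on simulated counts for 12776 genes with known changes: it recovered 53.7% of 1.5-fold and 98.5% of 4-fold changes for monocyte-progenitor-like, 61.2% and 93.9% for neutrophil-progenitor-like, 65.7% and 95.5% for erythroid-like and 47.8% and 95.5% for megakaryocyte-like cells. False calls made up 2.76% to 6.47% of the calls. The simulated means were the same in all classes, with no library effect, apart from 66 or 67 genes per fold changed up or down. A far larger part of the list genes was called in the data. The simulation therefore cannot say how the calls fare where many genes shift between classes or where scaling matters. Alternatives were DESeq2 1.42.0 with its size factors, upper-quartile scaling, no filter on low counts, no replicate block, 197 cells drawn per class and library, doublets kept, a stricter cell filter (1000 genes, 2000 UMIs, under 5% mitochondrial), Leiden resolution 0.5, z-scores over both libraries, list genes allowed in clustering, and each library left out. After the data were seen, 3 more were added: unnamed clusters joined to their nearest class, the cycling cluster joined to HSC/MPP-like, and HSC/MPP-like reduced to its core cluster.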

Results

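Single-cell RNA sequencing was carried out on haematopoietic stem and progenitor cells, the bone marrow cells from which blood lineages arise, in mice with a conditional knockout of Taf1 and in wild-type (WT) mice. Taf1 is the largest subunit of TFIID, the complex of TATA-binding protein (Tbp) and its associated factors that recognises core promoters and helps to load RNA polymerase II. The design asks how loss of Taf1 alters expression in these cells. There were 3 libraries of each genotype, and the design text gives 3 mice per genotype without tying a library to a mouse. The p-value for barcode numbers measures the spread between libraries, and those for expression measure the spread left between the class sums of these libraries once each library's own level is removed. Lists of cell barcodes were analysed for all 6 libraries, which share 1 list of 32285 genes. Counts of unique molecular identifiers (UMIs, each standing for 1 captured RNA molecule) were analysed for WT replicates 1 and 3. Expression in the Taf1 KO libraries and in WT replicate 2 was not analysed here, so the deletion of Taf1 was not checked and no gene was compared between genotypes.

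The Taf1 KO libraries held more cell barcodes than the WT libraries in this small series, by 26.9% on average, a difference that did not pass the permutation test used. There were 12109, 9790 and 11180 barcodes in the Taf1 KO libraries (11026 ± 1167, SD, n = 3) and 7337, 9742 and 8987 in the WT libraries (8689 ± 1229.9, SD, n = 3). The lowest Taf1 KO library lay above the highest WT library. An exact two-sided permutation test of the means gave p = 0.1, the smallest value this test can give for 3 against 3 libraries. A barcode number reflects loading and cell calling as well as the cells recovered; the design text gives 10000 cells sent per sample, and 2 libraries held more barcodes than that.

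**Figure D1:**
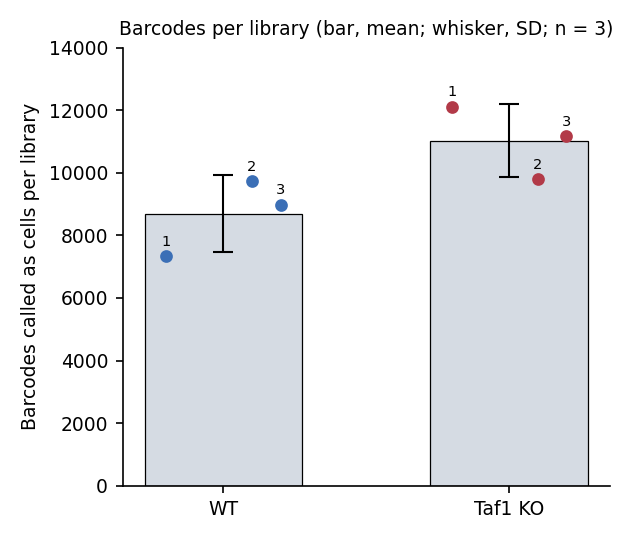
Number of barcodes called as cells in each library (points, numbered by replicate) for the WT and Taf1 KO groups, with the group mean as a bar from 0 and the SD as a whisker (n = 3 each). The Taf1 KO libraries sit between 9790 and 12109 barcodes and the WT libraries between 7337 and 9742.

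Few barcodes recurred between libraries. The 15 pairs of libraries shared between 14 and 45 barcodes, 412 in total and no barcode was found in 3 libraries. WT replicate 1 and Taf1 KO replicate 2 shared 34 barcodes where 19.7 were expected from the other pairs, and WT replicate 2 and Taf1 KO replicate 2 shared 15 where 27.9 were expected. Taf1 KO replicate 2 and WT replicate 3 shared 37 where 24.2 were expected. No pair passed the exact Poisson test adjusted over the pairs (lowest adjusted p = 0.0636).

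Depth was alike in the WT libraries with counts. WT replicate 1 held 183070808 UMIs over 7337 barcodes, with a median of 24195 UMIs and 4765 genes per barcode. WT replicate 3 held 229630494 UMIs over 8987 barcodes, with medians of 23639 and 4614. Mitochondrial transcripts made up 10% or more of the UMIs in 16.16% of the barcodes of WT replicate 1 and in 9.40% of those of WT replicate 3. After filtering, 5940 and 7826 cells were kept.

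Both WT libraries held the main branches of early haematopoiesis. Monocyte-progenitor-like cells, with F13a1 and Ms4a6c among the leading genes of each of their clusters, made up 28.8% (95% interval 27.7 to 29.99) of the kept cells in WT replicate 1 and 21.6% (20.6 to 22.5) in WT replicate 3. A cluster of 549 and 509 of these cells also had the neutrophil progenitor markers Hp, Prtn3 and Mpo among its leading genes. Neutrophil-progenitor-like cells, with Elane, Prtn3 and Ms4a3 leading most of their clusters and Mpo and Ctsg another, made up 17.1% (95% interval 16.1 to 18.1) of the kept cells in WT replicate 1 and 18.9% (18.1 to 19.8) in WT replicate 3. Erythroid-like cells, with Car1 and Ermap leading most of their clusters and the globin genes Hba-a1 and Hbb-bs another, made up 14.02% (95% interval 13.2 to 14.9) of the kept cells in WT replicate 1 and 20.6% (19.7 to 21.5) in WT replicate 3. HSC/MPP-like cells (haematopoietic stem cells and multipotent progenitors) made up 7.58% (95% interval 6.92 to 8.28) of the kept cells in WT replicate 1 and 9.07% (8.44 to 9.73) in WT replicate 3. Their core cluster, led by Hlf, Mecom and Procr, held 216 and 320 cells in replicates 1 and 3. It had 7 class markers among its 10 leading genes. The other cluster was larger, at 234 and 390 cells, and had 1 such marker, Adgrl4. Cd34, also among its leading genes, is not in the marker set and was a leading gene of a neutrophil-progenitor-like cluster too. Megakaryocyte-like cells, led by Pf4, Cavin2 and Treml1, made up 7.09% (95% interval 6.45 to 7.77) of the kept cells in WT replicate 1 and 4.78% (4.32 to 5.28) in WT replicate 3. Intervals are exact binomial (Clopper-Pearson) and cover counting error only.

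Smaller classes were basophil/mast-like cells (4.29% and 4.05% in replicates 1 and 3), lymphoid-primed-like cells (3.32% and 3.94%), dendritic-like cells (0.387% and 2.33%), T/NK-like cells (0.135% and 0.933%) and eosinophil-like cells (0.219% and 0.511%). The lymphoid-primed-like share depended on the setting. It was 9.01% and 13.7% at Leiden resolution 0.5 and 6.92% and 10.3% with unnamed clusters joined to their nearest class. With the stricter filter it was 6.11% and 7.35%, and with doublets kept 3.61% and 4.14%. A cluster led by Clec4d, Apoe and Trib2, nearest to erythroid-like cells by its markers, was left unnamed at 12.2% and 6.82%. Another unnamed cluster, led by the histone gene Hist1h2ap and the mitotic genes Nusap1 and Cenpf, held 3.603% and 6.38%, and lymphoid-primed-like was its nearest class by markers. A B-lineage-like class of similar share was named with the stricter filter (3.38% and 6.42%), with z-scores over both libraries (2.61% and 6.095%) and with list genes in clustering (3.13% and 6.16%). Whether it holds the same cells was not tested. A cluster of low-UMI barcodes held 1.28% and 0.115%. The rule that left these clusters unnamed was set after the clusters were seen. Mean shares over the 2 libraries were 25.2% ± 5.14 (SD, n = 2) for monocyte-progenitor-like, 17.3% ± 4.63 for erythroid-like and 8.32% ± 1.06 for HSC/MPP-like cells. Shares of the HSC/MPP-like class ranged from 4.04% to 13.3% over the other ways of filtering and clustering tried.

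**Figure D2:**
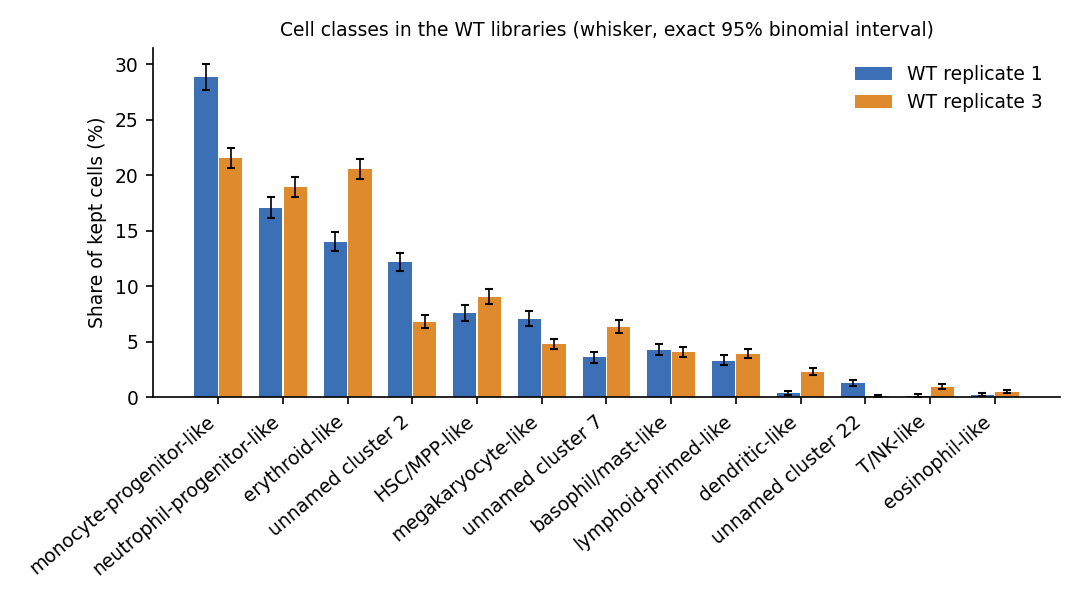
Share of kept cells (percent) in each class or unnamed cluster for WT replicate 1 (blue) and WT replicate 3 (orange), with exact 95% binomial intervals as whiskers. Monocyte-progenitor-like cells are the largest class in both libraries in the main setting, at 28.8% and 21.6%. With doublets kept and cells clustered anew they held 18.2% and 15.3%, below neutrophil-progenitor-like cells at 27.8% and 25.9%.

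Taf1 was counted in every class tested in WT marrow. As a share of UMIs, its class means lay within a factor of 2 of each other. This share was highest in the erythroid-like and megakaryocyte-like classes and lowest in the neutrophil-progenitor-like class. The gene (ENSMUSG00000031314) lies on chromosome X, from 101532734 to 101601789 on the plus strand of GRCm38 (mm10), and is protein-coding. Background RNA in the droplets was not estimated. Over all kept cells it was counted 6223 times in WT replicate 1 (36.4 CPM, its count scaled by the total of the library) and 8960 times in WT replicate 3 (42.1 CPM). Its class means (CPM ± SD, n = 2 libraries) were 51.7 ± 3.22 in erythroid-like, 49.9 ± 5.98 in megakaryocyte-like, 43.5 ± 0.879 in basophil/mast-like, 39.5 ± 5.35 in HSC/MPP-like, 37.2 ± 6.04 in lymphoid-primed-like, 36.6 ± 1.91 in monocyte-progenitor-like and 33.1 ± 4.42 in neutrophil-progenitor-like cells. The difference across the 7 classes passed edgeR's quasi-likelihood test (adjusted p = 6.65e-05). These values and the Taf1 comparisons that follow are of shares of UMIs, and the order per cell can differ. Neutrophil-progenitor-like cells held 915 Taf1 UMIs in 1014 cells of WT replicate 1 and 1316 in 1483 of WT replicate 3. HSC/MPP-like cells held 310 in 450 and 478 in 710, fewer per cell.

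Between committed classes, Taf1 was lower in neutrophil-progenitor-like than in erythroid-like cells (-0.64 ± 0.087 on the log2 scale, SE, adjusted p = 1.43e-05) and than in megakaryocyte-like cells (-0.59 ± 0.095, adjusted p = 0.000111). Monocyte-progenitor-like cells were also below erythroid-like cells (-0.50 ± 0.086, adjusted p = 0.00014) and below megakaryocyte-like cells (-0.44 ± 0.093, adjusted p = 0.00104). Erythroid-like and megakaryocyte-like cells differed by 0.052 ± 0.093 (adjusted p = 0.643), and monocyte- and neutrophil-progenitor-like cells by 0.15 ± 0.088 (adjusted p = 0.237), neither of which passed. The gap between erythroid-like and neutrophil-progenitor-like cells was 0.62 with upper-quartile scaling, 0.67 with DESeq2, and 0.72 and 0.57 in replicates 1 and 3 taken singly. These contrasts between committed classes were chosen after the data were seen.

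Against HSC/MPP-like cells the differences in Taf1 were smaller than those between committed classes that passed. Taf1 was higher in erythroid-like cells by 0.39 ± 0.093 (adjusted p = 0.00183) and in megakaryocyte-like cells by 0.33 ± 0.10 (adjusted p = 0.0188), and lower in neutrophil-progenitor-like cells (-0.26 ± 0.095, adjusted p = 0.0305). Values in monocyte-progenitor-like (-0.11 ± 0.094, adjusted p = 0.331), basophil/mast-like (0.14 ± 0.11, adjusted p = 0.339) and lymphoid-primed-like cells (-0.088 ± 0.11, adjusted p = 0.689) did not pass. These calls are sensitive to processing: of 13 alternatives, 11 kept the erythroid-like call, 8 the megakaryocyte-like call and 7 the neutrophil-progenitor-like call, and 3 called Taf1 in monocyte-progenitor-like cells, each of them lower. For genes and lists named after this, the number of alternatives that kept a call is given as kept in so many of the total, wherever some lost it.

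**Figure D3:**
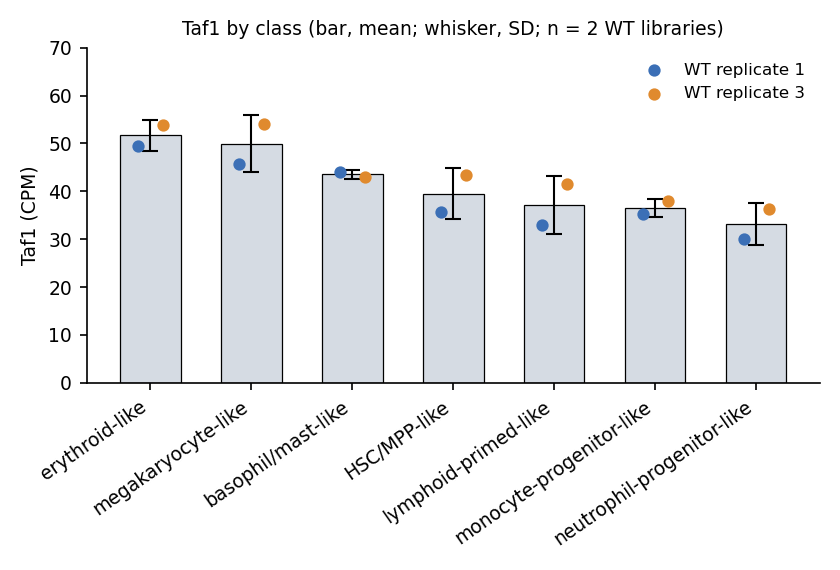
Taf1 level (CPM) in 7 cell classes of the WT libraries; points are WT replicate 1 (blue) and WT replicate 3 (orange), bars the mean from 0 and whiskers the SD (n = 2). Means run from 33.1 CPM in neutrophil-progenitor-like to 51.7 CPM in erythroid-like cells.

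With TMM scaling, TFIID subunits, Taf1 included, were higher in the committed classes than in HSC/MPP-like cells more often than lower, most often in erythroid-like cells. Of 15 tested TFIID genes, 9 were higher and 1 lower in erythroid-like cells, 6 and 2 in monocyte-progenitor-like, 5 and 2 in neutrophil-progenitor-like (4 and 5 with upper-quartile scaling, the median turning from 0.13 to -0.035) and 3 and 1 in megakaryocyte-like cells, with the same counts when adjusted over the list alone. Of all 693 tested list genes, 367, 365, 358 and 153 were higher and 176, 147, 162 and 139 lower in the same order of classes. The share of TFIID genes called higher lay above that of all list genes in erythroid-like cells only, and below it in the other classes. In erythroid-like cells the largest rises were Taf12 (1.72 ± 0.12), Taf10 (1.18 ± 0.094) and Taf5 (1.18 ± 0.096), as log2 fold change ± SE; Taf12 and Taf10 carry histone-fold domains and Taf5 is a scaffold subunit. Taf11 (0.69 ± 0.096), Taf2 (0.64 ± 0.10), Tbp (0.50 ± 0.13, adjusted p = 0.00289, kept in 11 of 13) and Taf6 (0.26 ± 0.097, adjusted p = 0.0289, kept in 6 of 13) also rose there. Tbp (ENSMUSG00000014767, chromosome 17, 15499888 to 15528379) did not pass in the other comparisons (0.042 in megakaryocyte-like, 0.27 in monocyte- and 0.27 in neutrophil-progenitor-like cells). Taf5 (0.73 ± 0.097, kept in 12 of 13), Taf12 (0.66 ± 0.12), Taf10 (0.59 ± 0.094), Taf11 (0.54 ± 0.096, kept in 12 of 13), Taf6 (0.40 ± 0.097, kept in 9 of 13) and Taf2 (0.35 ± 0.11, kept in 4 of 13) rose in monocyte-progenitor-like cells. Neutrophil-progenitor-like cells had higher Taf10 (0.74 ± 0.094), Taf5 (0.71 ± 0.098), Taf12 (0.69 ± 0.12), Taf11 (0.66 ± 0.096) and Taf2 (0.38 ± 0.11, kept in 4 of 13). In megakaryocyte-like cells, Taf5 (0.66 ± 0.11, kept in 11 of 13) and Taf10 (0.41 ± 0.095, kept in 12 of 13) rose beside Taf1. Taf7, which binds Taf1 and restrains its enzymatic activity, was lower in erythroid-like (-0.47 ± 0.11), megakaryocyte-like (-0.49 ± 0.12), monocyte-progenitor-like (-0.30 ± 0.11) and neutrophil-progenitor-like cells (-0.33 ± 0.11), calls kept in 10, 10, 10 and 10 of 13 alternatives. In monocyte-progenitor-like cells its call and sign were lost when doublets were kept. The Taf7 falls are in shares of UMIs. HSC/MPP-like cells held 332 Taf7 UMIs in 450 cells of WT replicate 1 and 542 in 710 of WT replicate 3. Erythroid-like cells held 880 in 833 and 2210 in 1610, more per cell, as did monocyte- and neutrophil-progenitor-like cells. Megakaryocyte-like cells held 250 in 421 and 271 in 374, fewer per cell. Taf9b, a paralog of Taf9, was counted under 10 CPM. It was higher in erythroid-like (0.71 ± 0.27, adjusted p = 0.0291, kept in 6 of 13) cells. Taf9b was not called in megakaryocyte-like (0.78 ± 0.31, adjusted p = 0.067, passing in 4 of 13) and neutrophil-progenitor-like (-0.71 ± 0.30, adjusted p = 0.0556, passing in 6 of 13) cells. It was lower in monocyte-progenitor-like (-0.98 ± 0.30, adjusted p = 0.0119, kept in 11 of 13) cells. As a set, TFIID passed camera in erythroid-like (camera adjusted p = 0.0275; adjusted p = 0.577 with an estimated correlation) and megakaryocyte-like cells (camera adjusted p = 0.0492; adjusted p = 0.577 with an estimated correlation), not in monocyte-progenitor-like (camera adjusted p = 0.193; adjusted p = 0.587 with an estimated correlation) or neutrophil-progenitor-like cells (camera adjusted p = 0.368; adjusted p = 0.648 with an estimated correlation). The megakaryocyte-like call was kept in 2 and the erythroid-like call in 7 of the 12 alternatives with a set test.

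The remaining lists were compared between each of the 4 largest classes and HSC/MPP-like cells. Values in parentheses after a gene are log2 fold changes from edgeR over 12776 genes, ± an SE derived from the gene's F statistic. They compare shares of UMIs and not amounts per cell. Each gene named by rule had the same sign in both libraries. Words such as highest, lowest, most or led by rank only the genes that passed, with that same sign and at least 10 CPM in 1 of the compared classes; genes with lower counts can lie further out. Because the HSC/MPP-like sums serve in every comparison, calls in different classes are not independent. Upper-quartile scaling moved the median log2 fold change of all genes from 0.021 to -0.16 in monocyte-progenitor-like, from -0.013 to -0.17 in neutrophil-progenitor-like, from -0.036 to -0.22 in erythroid-like and from 0.0088 to -0.034 in megakaryocyte-like cells. Of 84 set tests, 47 passed with the preset correlation and 0 with an estimated one (8 had an unadjusted p under 0.05).

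Monocyte-progenitor-like cells had higher oxidative phosphorylation, RNA polymerase II and mitotic genes than HSC/MPP-like cells, and lower interferon response genes. Across the lists, 365 of the 693 tested genes were higher and 147 lower, or 368 and 146 when adjusted over the list alone; with upper-quartile scaling the split was 286 and 189. All 12 tested RNA polymerase II subunits were higher, Polr2l (0.94 ± 0.13) most (camera adjusted p = 0.00198; adjusted p = 0.577 with an estimated correlation), and so were 75 of 76 oxidative phosphorylation genes, led by cytochrome c, Cycs (1.42 ± 0.098, adjusted p = 4.46e-08). For oxidative phosphorylation genes, camera gave adjusted p = 1.04e-18 (adjusted p = 0.577 with an estimated correlation). Ribosomal protein genes were higher for 59 of 79, led by Rpl41 (0.55 ± 0.078), a count that fell to 18 with upper-quartile scaling. For ribosomal protein genes, camera gave adjusted p = 2.86e-06 (adjusted p = 0.640 with an estimated correlation). The lysosome list gave 15 higher and 4 lower of 27, with a higher Ctsz (2.02 ± 0.096), a cathepsin, and a lower Cd63 (-2.19 ± 0.23). For lysosome genes, camera gave adjusted p = 0.00408 (adjusted p = 0.577 with an estimated correlation). Interferon response genes gave 2 higher and 34 lower of 43; Rtp4 (-5.79 ± 0.19, adjusted p = 1.66e-10) went from 30.8 ± 0.802 CPM (SD) in HSC/MPP-like to 0.556 ± 0.0866 CPM, while the guanylate-binding gene Gbp3 (1.11 ± 0.16) was higher. For interferon response genes, camera gave adjusted p = 6.85e-10 (adjusted p = 0.407 with an estimated correlation).

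Cytokine receptor and surface signalling genes in the same cells gave 14 higher and 25 lower of 47, with a higher Il6st (2.50 ± 0.20), the shared gp130 receptor subunit, and a lower Tie1 (-2.68 ± 0.21), an endothelial and stem cell receptor kinase. For receptor and surface signalling genes, camera gave adjusted p = 0.0495, kept in 6 of 12 (adjusted p = 0.648 with an estimated correlation). Other general transcription factors gave 12 higher and 1 lower of 17 (camera adjusted p = 0.0088; adjusted p = 0.577 with an estimated correlation), with Gtf2h5 (0.86 ± 0.079) higher and Gtf2h3 (-0.72 ± 0.12) lower. Heme and iron genes gave 7 higher and 2 lower of 21: Alas1 (2.50 ± 0.12), a rate-limiting enzyme of heme synthesis, rose and the transferrin receptor gene Tfr2 (-4.13 ± 0.17) fell. In the cholesterol list (5 higher and 7 lower of 23, or 4 and 7 over the list alone) Fdps (1.93 ± 0.14) rose and Srebf2 (-1.29 ± 0.086) fell, and in the antioxidant list (12 higher and 5 lower of 23, or 14 and 5 over the list alone) Gsr (1.88 ± 0.12) rose and Gclm (-0.67 ± 0.11) fell. Immediate early and stress genes gave 7 higher and 17 lower of 31, or 8 and 17 over the list alone, with a lower Zfp36l1 (-3.24 ± 0.20). For immediate early and stress genes, camera gave adjusted p = 0.0358, kept in 7 of 12 (adjusted p = 0.640 with an estimated correlation). Glycolysis genes (Pgam1 1.43 ± 0.12 and Slc2a3 -1.70 ± 0.12) gave 12 higher and 7 lower of 23. Mediator (Med21 1.54 ± 0.11 largest) gave 14 higher and 2 lower of 33, or 14 and 1 over the list alone but with a median that turned from 0.12 to -0.055 with upper-quartile scaling. Pausing and elongation genes gave 10 higher and 3 lower of 27 but 6 and 7 with upper-quartile scaling, and epigenetic and cohesin genes (Idh1 2.01 ± 0.12 and Tet1 -2.12 ± 0.17) 12 higher and 16 lower of 40, or 13 and 16 over the list alone. SAGA gave 6 higher and 4 lower of 18 but 4 and 9 with upper-quartile scaling, p53 targets 3 higher and 10 lower of 23 and apoptosis genes 7 higher and 6 lower of 22 but 5 and 7 with upper-quartile scaling. None of these 7 lists passed camera, nor did the heme, cholesterol and antioxidant lists. S phase genes gave 24 higher and 2 lower of 41, led by Rrm2 (1.93 ± 0.13). For S phase genes, camera gave adjusted p = 0.000113 (adjusted p = 0.577 with an estimated correlation). G2 and M phase genes gave 51 higher and 0 lower of 52, led by Ube2c (4.36 ± 0.26, adjusted p = 1.29e-08). For G2 and M phase genes, camera gave adjusted p = 4.98e-22 (adjusted p = 0.407 with an estimated correlation). With the unnamed cycling cluster joined to HSC/MPP-like the count was 21 higher and 0 lower. That cluster is led by genes of this list, so joining it raises the HSC/MPP-like level by construction. The class names also treat cycling cells unevenly. The unnamed cluster stayed out of every class for want of a class marker. A monocyte-progenitor-like cluster of 211 and 239 cells, with Ube2c among its leading genes, kept its class. The main count therefore cannot tell higher G2 and M phase expression from the way the classes were drawn.

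Neutrophil-progenitor-like cells had every tested oxidative phosphorylation gene higher than HSC/MPP-like cells, and epigenetic regulators more often lower than higher. Across the lists, 358 of the 693 tested genes were higher and 162 lower, or 360 and 163 when adjusted over the list alone; with upper-quartile scaling the split was 294 and 217. All 76 oxidative phosphorylation genes were higher, again led by Cycs (1.57 ± 0.098, adjusted p = 2.67e-08). For oxidative phosphorylation genes, camera gave adjusted p = 8.33e-21 (adjusted p = 0.577 with an estimated correlation). Ribosomal protein genes were higher for 66 of 79 (67 when adjusted over the list alone and 40 with upper-quartile scaling), led by Rpl41 (0.64 ± 0.078) (camera adjusted p = 1.15e-08; adjusted p = 0.603 with an estimated correlation), and RNA polymerase II genes for 11 of 12. For RNA polymerase II genes, camera gave adjusted p = 0.00133 (adjusted p = 0.577 with an estimated correlation). Heme and iron genes gave 11 higher and 1 lower of 21 (camera adjusted p = 0.00953; adjusted p = 0.587 with an estimated correlation); Alas1 (3.68 ± 0.12, adjusted p = 3.27e-10) stood at 582 ± 41.8 against 45.6 ± 5.37 CPM in HSC/MPP-like cells. Epigenetic and cohesin genes of myeloid malignancy gave 7 higher and 20 lower of 40, with Tet1 (-1.61 ± 0.17), a DNA demethylase, lower and Idh1 (1.87 ± 0.12) higher. For epigenetic and cohesin genes, camera gave adjusted p = 0.038, kept in 8 of 12 (adjusted p = 0.577 with an estimated correlation). Interferon response genes gave 2 higher and 35 lower of 43, with Iigp1 (-4.49 ± 0.24, adjusted p = 7.30e-09) lower. For interferon response genes, camera gave adjusted p = 6.89e-10 (adjusted p = 0.407 with an estimated correlation).

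Receptor and surface signalling genes gave 9 higher and 28 lower of 47 in neutrophil-progenitor-like cells, among them a higher interferon gamma receptor gene Ifngr1 (2.46 ± 0.14) and a lower interleukin-1 receptor gene Il1r1 (-2.96 ± 0.21). For receptor and surface signalling genes, camera gave adjusted p = 0.00221 (adjusted p = 0.587 with an estimated correlation). Immediate early and stress genes gave 3 higher and 19 lower of 31, or 4 and 19 over the list alone, with a lower Egr1 (-3.96 ± 0.50), a serum-induced transcription factor, and a higher Rhob (1.22 ± 0.15). For immediate early and stress genes, camera gave adjusted p = 0.000999 (adjusted p = 0.577 with an estimated correlation). The lysosome list gave 16 higher and 4 lower of 27, or 18 and 4 over the list alone, with Cd63 (1.67 ± 0.23) up. For lysosome genes, camera gave adjusted p = 0.00845 (adjusted p = 0.577 with an estimated correlation). Antioxidant genes gave 13 higher and 5 lower of 23: glutathione reductase, Gsr (2.89 ± 0.12), rose and Prdx4 (-1.79 ± 0.15) fell. For antioxidant genes, camera gave adjusted p = 0.038, kept in 9 of 12 (adjusted p = 0.587 with an estimated correlation). Other general transcription factors gave 11 higher and 0 lower of 17, led by Gtf2h5 (0.95 ± 0.080). For other general transcription factor genes, camera gave adjusted p = 0.00284 (adjusted p = 0.577 with an estimated correlation). The lists that did not pass camera were Mediator (15 higher and 7 lower of 33, Med21 2.10 ± 0.11 and Med13l -0.76 ± 0.095), glycolysis (13 higher and 4 lower of 23, or 13 and 5 over the list alone, Hk3 1.61 ± 0.21 and Slc2a3 -2.01 ± 0.12), cholesterol synthesis (7 higher and 3 lower of 23, or 5 and 3 over the list alone but 5 and 11 with upper-quartile scaling), pausing and elongation (10 higher and 4 lower of 27 but 6 and 7 with upper-quartile scaling), SAGA (5 higher and 4 lower of 18 but 4 and 10 with upper-quartile scaling, Sf3b5 0.98 ± 0.082 and Atxn7 -0.99 ± 0.12), p53 targets (6 higher and 11 lower of 23, with the pro-apoptotic Bbc3 -1.44 ± 0.18 lower) and apoptosis (5 higher and 9 lower of 22). S phase genes gave 20 higher and 5 lower of 41, with Rrm2 (2.08 ± 0.13) highest. For S phase genes, camera gave adjusted p = 0.0112, kept in 11 of 12 (adjusted p = 0.615 with an estimated correlation). For G2 and M phase genes the count was 47 higher and 1 lower of 52 (camera adjusted p = 8.57e-16, kept in 11 of 12; adjusted p = 0.407 with an estimated correlation), and it turned to 5 higher and 28 lower with the cycling cluster joined to HSC/MPP-like and to 7 higher and 24 lower with doublets kept. Keeping doublets meant clustering anew, and HSC/MPP-like then held 10.00% and 14.02% of cells, so that turn comes with another class boundary.

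Erythroid-like cells had higher heme synthesis and transcription machinery genes than HSC/MPP-like cells, and mostly lower cytokine receptor genes. Across the lists, 367 of the 693 tested genes were higher and 176 lower, or 365 and 176 when adjusted over the list alone; with upper-quartile scaling the split was 285 and 240. Heme and iron genes gave 18 higher and 2 lower of 21; Cpox (3.78 ± 0.20, adjusted p = 1.07e-09), a mitochondrial enzyme of heme synthesis, stood at 266 ± 76.6 against 19.6 ± 3.32 CPM, while Alas1 (-1.03 ± 0.12), the housekeeping isoform of the entry enzyme, was lower. For heme and iron genes, camera gave adjusted p = 1.32e-05 (adjusted p = 0.577 with an estimated correlation). Receptor and surface signalling genes gave 5 higher and 36 lower of 47: Tie1 (-6.35 ± 0.30, adjusted p = 2.90e-10) fell and Il1rl1 (5.17 ± 0.21, adjusted p = 6.88e-11), the interleukin-33 receptor gene, rose from 0.766 ± 0.0583 to 27.6 ± 1.07 CPM. For receptor and surface signalling genes, camera gave adjusted p = 2.66e-06 (adjusted p = 0.577 with an estimated correlation). RNA polymerase II genes gave 11 higher and 0 lower of 12 (camera adjusted p = 0.000999; adjusted p = 0.577 with an estimated correlation), other general transcription factors 14 higher and 0 lower of 17, led by Gtf2h3 (1.40 ± 0.11) (camera adjusted p = 0.000885; adjusted p = 0.577 with an estimated correlation), Mediator 24 higher and 3 lower of 33, with Med10 (1.33 ± 0.10) and Cdk19 (-1.49 ± 0.13) named by the rule (camera adjusted p = 0.00345; adjusted p = 0.515 with an estimated correlation), and pausing and elongation genes 18 higher and 1 lower of 27, led by Ell2 (3.37 ± 0.15, adjusted p = 1.71e-10), an elongation factor. For pausing and elongation genes, camera gave adjusted p = 0.00133 (adjusted p = 0.407 with an estimated correlation). SAGA, which shares subunits with TFIID, gave 8 higher and 3 lower of 18 (Tada2b 1.93 ± 0.17 and Usp22 -1.77 ± 0.11) and did not pass camera (adjusted p = 0.264). The SAGA list holds no gene of the TFIID list, so shared subunits were counted with TFIID only.

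Oxidative phosphorylation genes were higher in erythroid-like cells for 74 of 76, led by Cyc1 (1.49 ± 0.10). For oxidative phosphorylation genes, camera gave adjusted p = 4.18e-14 (adjusted p = 0.577 with an estimated correlation). Interferon response genes gave 2 higher and 33 lower of 43, with Ifi203 (-4.94 ± 0.16, adjusted p = 1.52e-11) lower. For interferon response genes, camera gave adjusted p = 8.07e-06 (adjusted p = 0.577 with an estimated correlation). Immediate early and stress genes gave 5 higher and 21 lower of 31, with the phosphatase gene Dusp5 (-5.40 ± 0.28) lower and the chaperone gene Hsph1 (2.07 ± 0.19) higher. For immediate early and stress genes, camera gave adjusted p = 0.00221 (adjusted p = 0.577 with an estimated correlation). Lysosome genes gave 4 higher and 15 lower of 27, with Grn (-2.67 ± 0.14), progranulin, lowest. For lysosome genes, camera gave adjusted p = 0.0368, kept in 8 of 12 (adjusted p = 0.603 with an estimated correlation). The antioxidant list gave 17 higher and 3 lower of 23, or 18 and 3 over the list alone, led by Nqo1 (2.99 ± 0.28). For antioxidant genes, camera gave adjusted p = 0.00133 (adjusted p = 0.577 with an estimated correlation). Apoptosis genes moved both ways (6 higher and 9 lower of 22): Bcl2 (-3.54 ± 0.27, adjusted p = 3.81e-08), which blocks apoptosis, fell from 119 ± 0.280 to 10.9 ± 6.73 CPM. Glycolysis genes gave 5 higher and 13 lower of 23, with Pfkm (1.49 ± 0.18) and Hk3 (-5.21 ± 0.30) named by the rule, p53 targets 7 higher and 11 lower of 23, with Cdkn1a (-3.37 ± 0.35) lower, cholesterol synthesis 8 higher and 6 lower of 23 but 4 and 7 with upper-quartile scaling and epigenetic and cohesin genes 12 higher and 13 lower of 40, or 12 and 12 over the list alone; these lists did not pass camera. Ribosomal protein genes gave 41 higher and 2 lower of 79, or 38 and 2 over the list alone (camera adjusted p = 0.00221, kept in 11 of 12; adjusted p = 0.712 with an estimated correlation), and with upper-quartile scaling 17 higher and 26 lower, so their direction depends on the scaling. S phase genes gave 28 higher and 4 lower of 41, led by E2f8 (1.99 ± 0.11). For S phase genes, camera gave adjusted p = 0.000885 (adjusted p = 0.577 with an estimated correlation). G2 and M phase genes gave 51 higher and 0 lower of 52, or 51 and 1 over the list alone, led by Ube2c (4.59 ± 0.26) (camera adjusted p = 5.77e-17; adjusted p = 0.407 with an estimated correlation), and 32 higher and 2 lower with the cycling cluster joined to HSC/MPP-like.

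Megakaryocyte-like cells had the fewest list genes called against HSC/MPP-like cells. Across the lists, 153 of the 693 tested genes were higher and 139 lower, or 147 and 141 when adjusted over the list alone; with upper-quartile scaling the split was 136 and 166. With equal cells per class it was still the fewest (236 called, against 405, 428 and 485 in monocyte-progenitor-like, neutrophil-progenitor-like and erythroid-like cells). Equal cells did not make depth equal. Megakaryocyte-like cells had medians of 18011 and 16845.5 UMIs in replicates 1 and 3, and those other classes 27705 or more. The part of depth in the low number was not tested. The number called higher ranged from 77 to 261 over the alternatives, lowest with doublets kept and highest with HSC/MPP-like reduced to its core cluster. Interferon response genes gave 0 higher and 30 lower of 43, or 1 and 34 over the list alone, with Ifit1 (-3.02 ± 0.42, adjusted p = 7.32e-05) lower. For interferon response genes, camera gave adjusted p = 5.58e-10 (adjusted p = 0.407 with an estimated correlation). Receptor and surface signalling genes gave 5 higher and 26 lower of 47, or 5 and 27 over the list alone: the granulocyte colony-stimulating factor receptor gene Csf3r (-4.14 ± 0.23, adjusted p = 1.11e-08) fell and Tgfbr3 (2.46 ± 0.25), a transforming growth factor co-receptor, rose. For receptor and surface signalling genes, camera gave adjusted p = 0.000885 (adjusted p = 0.577 with an estimated correlation). Lysosome genes gave 1 higher and 16 lower of 27, or 2 and 16 over the list alone, with Ctsl (-1.27 ± 0.13) and Lamp1 (0.54 ± 0.094) named by the rule. For lysosome genes, camera gave adjusted p = 0.000985 (adjusted p = 0.577 with an estimated correlation). Oxidative phosphorylation genes gave 21 higher and 1 lower of 76, or 15 and 1 over the list alone (camera adjusted p = 0.00025, kept in 9 of 12; adjusted p = 0.679 with an estimated correlation), a count that became 3 higher and 3 lower with the cycling cluster joined to HSC/MPP-like and 62 higher and 0 lower with the core cluster alone. Ribosomal protein genes gave 2 higher and 13 lower of 79, or 1 and 7 over the list alone, with Rpl21 (0.26 ± 0.059, kept in 12 of 13) and Rpl37 (-0.33 ± 0.062) named by the rule. For ribosomal protein genes, camera gave adjusted p = 0.0369, kept in 7 of 12 (adjusted p = 0.804 with an estimated correlation). With upper-quartile scaling the count was 1 higher and 31 lower; with the core cluster alone they gave 16 higher and 2 lower.

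Among transcription lists in megakaryocyte-like cells, Mediator gave 5 higher and 2 lower of 33 but with a median that turned from 0.025 to -0.019 with upper-quartile scaling, with Med12l (2.12 ± 0.21, adjusted p = 3.05e-06) highest, other general transcription factors 6 higher and 0 lower of 17, or 6 and 2 over the list alone, RNA polymerase II 2 higher and 0 lower of 12, with Polr2e (0.40 ± 0.082) highest, and SAGA 2 higher and 3 lower of 18, or 2 and 2 over the list alone. None of these passed camera. Pausing and elongation genes gave 6 higher and 0 lower of 27, or 4 and 0 over the list alone, with Hexim1 (0.60 ± 0.15, kept in 10 of 13) highest. For pausing and elongation genes, camera gave adjusted p = 0.0473, kept in 4 of 12 (adjusted p = 0.515 with an estimated correlation). The survival gene Bcl2l1 (1.10 ± 0.18, adjusted p = 0.000269) rose and Bcl2l11 (-1.11 ± 0.28) fell in the apoptosis list (3 higher and 5 lower of 22). In the cholesterol list (3 higher and 2 lower of 23) Stard4 (1.20 ± 0.11) rose and in the antioxidant list (4 higher and 3 lower of 23) Prdx4 (1.02 ± 0.15) rose and Gpx1 (-0.74 ± 0.079) fell. Heme and iron genes gave 5 higher and 3 lower of 21 and glycolysis 4 higher and 9 lower of 23, or 4 and 10 over the list alone, with Hk3 (-4.02 ± 0.36) lowest. The p53 targets gave 3 higher and 7 lower of 23, with Cdkn1a (-2.04 ± 0.39, kept in 12 of 13) lowest. Immediate early and stress genes gave 6 higher and 9 lower of 31, with Dusp5 (-3.58 ± 0.32) lowest, and epigenetic and cohesin genes 7 higher and 7 lower of 40 but 6 and 9 with upper-quartile scaling, with Rad21 (0.85 ± 0.088, kept in 11 of 13) and Tet1 (-0.57 ± 0.18, kept in 7 of 13) named by the rule. S phase genes gave 15 higher and 2 lower of 41, or 16 and 3 over the list alone, led by E2f8 (2.11 ± 0.12). For S phase genes, camera gave adjusted p = 0.00348 (adjusted p = 0.587 with an estimated correlation). G2 and M phase genes gave 50 higher and 0 lower of 52, led by Ckap2l (4.14 ± 0.15) (camera adjusted p = 2.62e-27, kept in 10 of 12; adjusted p = 0.407 with an estimated correlation); with the cycling cluster joined to HSC/MPP-like the count was 4 higher and 10 lower and with doublets kept 3 higher and 11 lower.

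**Figure D4:**
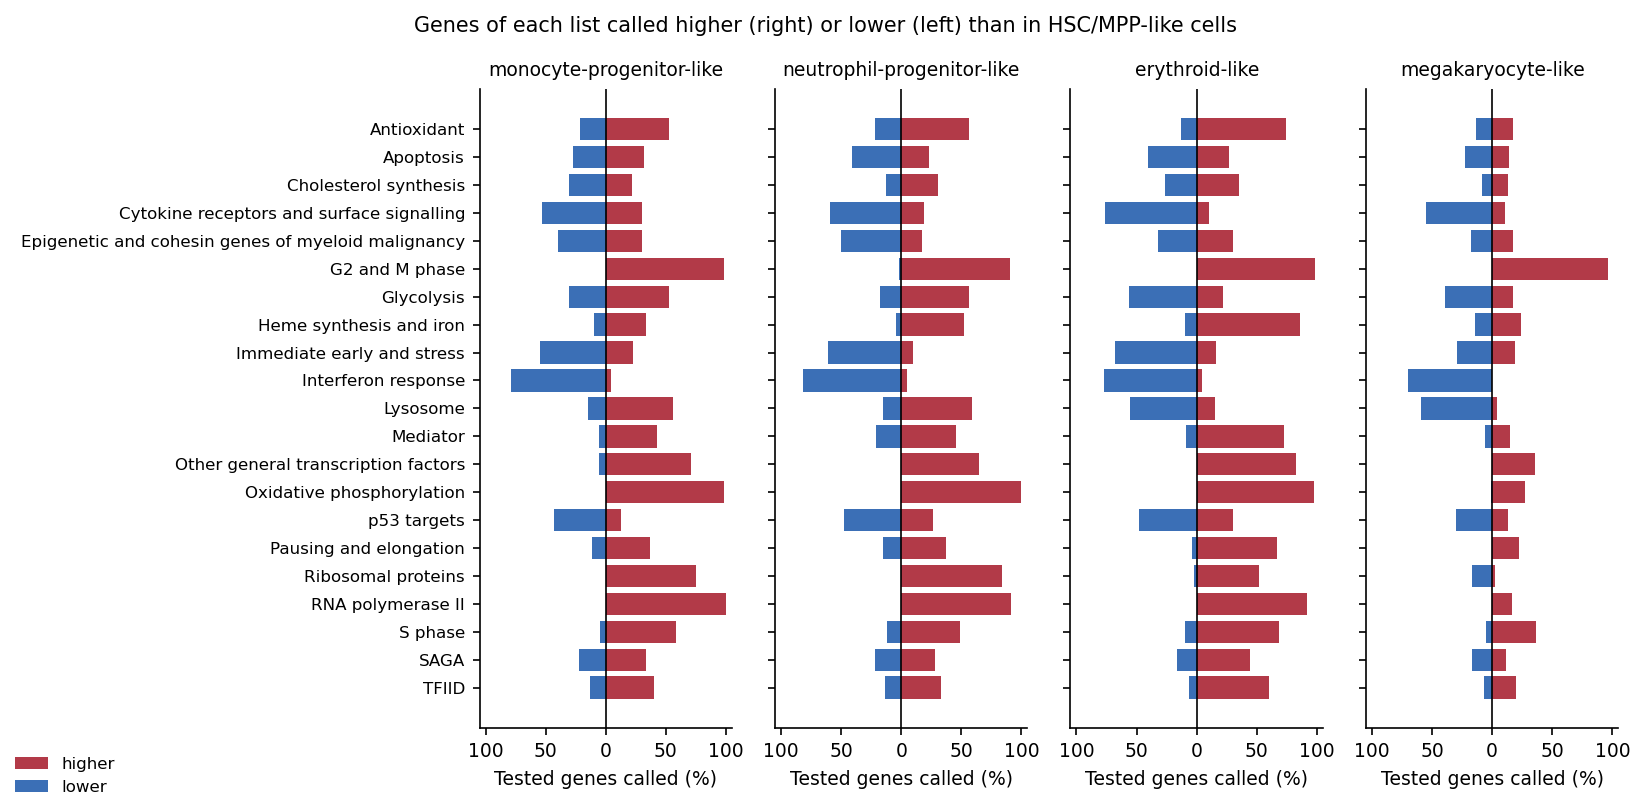
Percent of the tested genes of each list called higher (red, right) or lower (blue, left) than in HSC/MPP-like cells, in 4 classes of the WT libraries (edgeR, adjusted p under 0.05). Interferon response genes lie mostly to the left in each class (34, 35, 33 and 30 of 43); G2 and M phase genes called higher over the 4 classes sum to 199, 199 with unnamed clusters joined to their nearest class and 62 with a cycling cluster joined to HSC/MPP-like, and the direction of some lists, among them ribosomal proteins in erythroid-like and TFIID in neutrophil-progenitor-like cells, depends on the scaling.

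The WT libraries differed most in genes of the sex chromosomes. Summed over all kept cells, Xist, the RNA that silences 1 X chromosome in females, stood at 1105 CPM in WT replicate 1 and 0.357 CPM in WT replicate 3, and its antisense partner Tsix at 24.8 and 0.860 CPM. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d stood at 46.7, 40.3, 12.8 and 11.9 CPM in WT replicate 3 and together had 6 UMIs in WT replicate 1. The other genes among the 10 furthest apart were higher in WT replicate 3: the globins Hbb-bs (12.3-fold) and Hba-a1 (8.32-fold), whose paralogs are near-identical and can share reads, the immediate early gene Fosb (9.57-fold) and the heat shock gene Hspa1b (8.77-fold). Such ratios of sums reflect class shares as well as expression per cell. The erythroid-like cluster led by Hba-a1 and Hbb-bs held 1.20% of the kept cells in WT replicate 1 and 3.72% in WT replicate 3. Of 7736 genes with at least 10 CPM in a library, 74 were over 2-fold apart. By Xist and the Y-linked genes, WT replicate 1 came from female cells and WT replicate 3 from male cells, so they came from different mice. Sex cannot be told apart from any other difference between these libraries, Taf1 on chromosome X included. With 1 library a side, these differences have no replicate check.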

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

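Some signals were set aside before clustering or expression testing. In WT replicate 1, 16.16% of barcodes had 10% or more mitochondrial UMIs, against 9.40% in WT replicate 3; these barcodes count in the barcode numbers and entered no expression comparison. Xist stood at 1105 CPM in WT replicate 1, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together at 112 CPM in WT replicate 3, and these genes were kept out of the clustering; the labels give no sex.

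In this part, the tests of equal cell numbers, of single libraries, of scaling, of UMIs per cell and of shared barcodes were chosen after the result they bear on was seen. No biological explanation was tested, since the design's only groups are the genotypes. G2 and M phase genes were called higher 199 times over the 4 comparisons. With the same number of cells per class the sum was 194, which argues against unequal cell numbers. The class boundary stays open: joining the cycling cluster to HSC/MPP-like took the sum to 62, but that setting lowers the sum by construction, because Nusap1 and Cenpf lead that cluster and belong to the list. With unnamed clusters joined to their nearest class the sum was 199, with the core cluster alone 200 and with doublets kept and cells clustered anew 60. That last setting also moved the boundary: HSC/MPP-like grew to 10.00% and 14.02% of cells, near the 11.2% and 15.4% with the cycling cluster joined, so it is no separate test of doublets.

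Interferon response genes were called lower 132 times over the same comparisons. The medians per library, the highest of which was -0.96 over both libraries and 4 comparisons, argue against a single library carrying the pattern. The pattern stayed with the cycling cluster joined and with the core cluster alone, the lower sum being 119, which argues against these boundary shifts as its source. Its size followed the boundary. The list medians ran from -1.13 to -0.81 with the cycling cluster joined and from -1.84 to -1.50 with the core cluster alone. Both settings keep the core cluster in HSC/MPP-like, so they cannot say whether that cluster alone carries the pattern. A common factor on all genes of a class is argued against, because it would move the list and all genes alike, and the interferon median minus the all-gene median of the same fit was -0.96 at its highest over both libraries. Over all 4 comparisons amounts per cell stay open. The committed classes held more UMIs per cell. As UMIs per cell without scaling the interferon medians ran from -0.81 to -0.31, nearest 0 in erythroid-like cells (26 and 24 of 43 genes lower in replicates 1 and 3). Monocyte-progenitor-like medians were -0.38 and -0.59 (27 and 29 lower). In neutrophil-progenitor-like (-0.64 and -0.78, 30 and 31 lower) and megakaryocyte-like cells (-0.81 and -0.53, 33 and 33 lower) the values argue against unchanged interferon UMIs per cell. The set test did not pass with an estimated correlation (adjusted p = 0.407 in monocyte-progenitor-like cells).

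Shared barcodes could come from reads assigned to the wrong library. The 15 pairs did not share barcodes at a single rate (chi-square 31.1 on 14 degrees of freedom, p = 0.00534), with 6 pairs above and 9 below the number expected from the others. The pair furthest above, WT replicate 1 and Taf1 KO replicate 2, shared 1.73 times the expected number, with an exact Poisson p adjusted over the pairs of 0.0636. The uneven rates do not name a cause, and no single pair passed, so wrongly assigned reads stay open.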

How the results depend on the processing

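Alternatives that join unnamed clusters, join the cycling cluster or keep the core cluster alone were chosen after seeing the data; except where stated, the cause of a change was not tested. The barcode difference was 1662 to 2956 barcodes without each library in turn, 2311 without barcodes found in more than 1 library, and 1.27 as a ratio of geometric means. None of these settings could turn its sign, since the lowest Taf1 KO library lay above the highest WT library and few barcodes were shared. The HSC/MPP-like share became 13.3% with the cycling cluster joined and 4.04% with the core cluster alone, by construction, 12.01% with doublets kept, 5.91% with the stricter filter, 5.93% with z-scores over both libraries and 5.36% with list genes in clustering. A mean share counted as moved when it changed by at least the SD of the 2 libraries. Among the 4 classes compared with HSC/MPP-like, shares that moved were monocyte-progenitor-like 16.7% and neutrophil-progenitor-like 26.8% with doublets kept, neutrophil-progenitor-like 15.2% at resolution 0.5 and 15.6% with list genes in clustering, megakaryocyte-like 4.25% with z-scores over both libraries, and erythroid-like 26.8% with unnamed clusters joined. Smaller classes were not in this check, and the lymphoid-primed-like share rose to 9.01% and 13.7% in replicates 1 and 3 at resolution 0.5. Of the 8 counts of list genes higher or lower, 7 stayed within 1.5 times; genes higher in megakaryocyte-like cells numbered 77 with doublets kept, 232 with list genes in clustering, 78 with the cycling cluster joined and 261 with the core cluster alone. The TFIID median in erythroid-like cells lost its call with equal cells (0.28), doublets kept (0.19), z-scores over both libraries (0.37), list genes in clustering (0.34) and the core cluster (0.46). In megakaryocyte-like cells it lost it with upper-quartile scaling (0.19), equal cells (0.24), doublets kept (0.11), the stricter filter (0.25), resolution 0.5 (0.22), z-scores over both libraries (0.22), list genes in clustering (0.31), unnamed clusters joined (0.23), the cycling cluster joined (0.084) and the core cluster (0.24). Taf1 in erythroid-like cells did not pass with upper-quartile scaling (0.20) or equal cells (0.28); in megakaryocyte-like cells it did not pass without the replicate block (0.33), with equal cells (0.26), doublets kept (0.19), z-scores over both libraries (0.22) or the cycling cluster joined (0.16). In neutrophil-progenitor-like cells it did not pass without the low-count filter (-0.25) or the block (-0.26), with equal cells (-0.26), the stricter filter (-0.22), resolution 0.5 (-0.17) or the core cluster (-0.18), and in monocyte-progenitor-like cells it passed, lower, with upper-quartile scaling (-0.29), doublets kept (-0.22) and the cycling cluster joined (-0.27). With the stricter filter its value there turned to 0.012, not passing. G2 and M phase medians turned negative with doublets kept (-0.24 in neutrophil-progenitor-like and -0.16 in megakaryocyte-like cells) and with the cycling cluster joined (-0.32 and -0.16). The ribosomal protein median turned in erythroid-like cells with upper-quartile scaling (-0.036) and in megakaryocyte-like cells with the core cluster (0.044), and the oxidative phosphorylation median in megakaryocyte-like cells at resolution 0.5 (-0.0074) and with the cycling cluster joined (-0.00051). Single genes that turned with a call were Ung in megakaryocyte-like (0.23 with doublets kept, 0.027 with list genes in clustering, 0.24 with the cycling cluster joined, 0.49 with the core cluster), monocyte-progenitor-like (0.39, 0.36 and 0.59 with doublets kept, the cycling cluster joined and the core cluster) and erythroid-like cells (0.091 with the core cluster). With doublets kept, Bbc3 (0.0092) and Taf7 (0.0062) turned in monocyte-progenitor-like and Ube2c (-0.037, and -0.040 with the cycling cluster joined) in neutrophil-progenitor-like cells, where the core cluster also turned Cbx5 (0.12) and Dtl (0.092). Without a call in either fit, Tbp turned in megakaryocyte-like (-0.27 to -0.0025 in 5 alternatives), monocyte-progenitor-like (-0.096 and -0.022) and neutrophil-progenitor-like cells (-0.013 and -0.024), the latter 2 with doublets kept and the cycling cluster joined. Over all named genes, 2164 of 2314 values kept direction and call status, 113 lost the call, 13 gained it, 14 turned with a call and 10 without. For list medians 977 of 1092 kept both, 51 lost the call, 20 gained it, 8 turned with a call and 36 without, the latter in 16 of the 84 list and class pairs. The DESeq2 medians among the 1092 had no set test, so for them only the direction was compared. With 1 library left there are no residual degrees of freedom, so leaving out a library gave values and no counts: Taf1 ran from 0.32 to 0.47 in erythroid-like, 0.32 to 0.35 in megakaryocyte-like, -0.26 to -0.25 in neutrophil-progenitor-like and -0.19 to -0.021 in monocyte-progenitor-like cells. The TFIID median ran from 0.34 to 0.44, 0.21 to 0.23, 0.0051 to 0.23 and 0.091 to 0.40 in the same order.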

Other observations

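Classes differed in UMIs per cell. Erythroid-like cells had a median of 34141 UMIs in WT replicate 1 and 43620.5 in WT replicate 3, and HSC/MPP-like cells 16206 and 13162. Lymphoid-primed-like cells had 16306 and 11252. The unnamed cycling cluster had 33448 and 26202. Dendritic-like and T/NK-like cells, led by Cd74 and Ccl5, held larger shares of WT replicate 3 than of WT replicate 1, 2.33% against 0.387% and 0.933% against 0.135%. The median mitochondrial share was higher in HSC/MPP-like cells (4.11% and 4.09%) than in each of the 4 classes compared with them, among them erythroid-like (3.08% and 3.28%) and neutrophil-progenitor-like cells (2.61% and 2.65%). Its bearing on the comparisons, oxidative phosphorylation genes included, was not tested.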
